A study of Danio rerio with 18 samples.

How the data were processed

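The study measured messenger RNA in the digestive organs of zebrafish larvae at 6.5 days post fertilization, before and after a high-fat meal (5% egg yolk emulsion) or a low-fat meal (10% egg white). Per the labels, 18 samples fell into 6 groups of 3, and each sample pooled the intestine, liver and pancreas of 10 larvae. The 2 meals were given to separate cohorts, each with its own unfed control, and fed larvae were taken at 1 h and 4 h. The design text of the series states that the triplicates were prepared independently from separate crosses, so that spread between samples of a group includes differences between clutches. Per the labels' protocols, poly(A) libraries were sequenced as reads of 50 bases, with 6 samples per lane.

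Reads were aligned with TopHat2 and tested with edgeR, and positions refer to genome build Zv9, per the submitters' processing notes. Versions of these tools, the counting tool and the annotation release are not given in the sources used here. The data used were the authors' deposited table of their own comparisons, with 56754 Ensembl transcripts in rows and 0 columns of single samples. For each of 4 comparisons (1 h and 4 h after each meal against the unfed larvae of the same cohort) the authors gave a log2 fold change, a p-value and an adjusted p-value, and the table carries 1 average log2 CPM (counts scaled to the total of the library) per transcript, per the file headers. The adjusted p-values of the authors' deposited table equal a Benjamini-Hochberg adjustment over all 56754 rows, and the authors' marks of higher and lower transcripts equal an adjusted p under 0.05 split by the sign of the fold change; both were checked on the table. Totals of reads per sample and values of single samples were not analysed here, so the depth behind each value is unknown, and no interval that needs it is given.

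The precision of the authors' values was estimated from the table itself. The ratio of each log2 fold change to the normal score of its p-value gives an implied standard error. Over 2331 values with an average log2 CPM of at least 5 and a log2 fold change above 0.5 in size, this ratio had a median of 0.359, and 94.0% of the ratios lay within 2% of it. It rose to between 0.390 and 0.397 at a log2 CPM of 0 to 1. The standard error thus depended on the expression level and hardly on the transcript, as a dispersion shared by all transcripts would give, so the p-values do not carry each transcript's own spread between samples. A well expressed transcript had a 95% half-width of about 0.703 on the log2 scale. In the comparison 4 h after the low-fat meal, 2.39% of 1879 genes with a log2 CPM of at least 5 had an unadjusted p under 0.05, fewer than the 5% of chance, against 15.1%, 10.5% and 14.3% at 1 h and 4 h after the high-fat meal and 1 h after the low-fat meal.

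The tests planned for counts per sample could not be used with a table of comparisons, so fold changes and adjusted p-values against unfed larvae are the authors'. Counts of calls over transcripts use all rows. For all else, each symbol was represented by its transcript with the highest average (21227 symbols, of which 12828 had an average log2 CPM of at least 0 and are called genes below). The 18412 rows without a symbol entered only the counts of transcripts. Transcripts of a gene had much the same values in the authors' deposited table and may share reads: among 3760 genes with several transcripts of log2 CPM of at least 2, their log2 fold changes 1 h after the high-fat meal had a median range of 0.0351. In 752 rows the symbol joins several genes that overlap or share reads.

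The meals and the times were compared by subtracting the authors' log2 fold changes, with an approximate normal test on the implied standard errors and Benjamini-Hochberg adjustment over the 12828 genes. This test was chosen after the table was seen, since the plan was to run none. The difference between meals combined the errors of both comparisons. In the difference between 4 h and 1 h after a meal the unfed libraries cancel, and the error was set to the root of the mean of both squared errors. On simulated tables of 12828 genes with 200 changed genes, the test recovered 25% of differences of 1.5 and 89% of differences of 2.5 for the meal difference at 1 h (25% and 91% at 4 h), and 76% and 100% for 4 h against 1 h after the high-fat meal (75% and 100% after the low-fat meal). It made 1 false call among 115, 2 among 118, 7 among 183 and 12 among 187. The simulated errors were drawn from the same standard errors that the test used. These rates therefore leave out each transcript's own spread between samples and are not error rates of the real calls. A comparison of the unfed larvae of the 2 cohorts was not analysed here.

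The 31 gene lists (1004 named members and 3 lists given by a name pattern) and the rules for named genes were fixed before the data were examined, except where stated. After the table was seen, 1 pattern was narrowed so that it no longer took S6 kinases for ribosomal proteins. Members were matched by symbol or by older names paired with it in a RefSeq table of assembly GRCz12tu, used for names only. 30 lists had at least 5 measured genes, and the list of yolk proteins had none. Lists were tested with the competitive camera test of limma 3.58.1 in R 4.3.3 on the normal scores, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists within each comparison. A correlation estimated from the data needs values of single samples, so a stricter preset of 0.05 was used in its place, chosen after the table was seen. Each list's median was also placed among those of 10000 random lists of the same size, matched on expression in 10 bins. In a simulation of 12828 genes, the list test found a list of 30 genes that were each shifted by 1 standard error of a gene. It gave an unadjusted p under 0.05 to 0 of 100 unshifted lists. Genes were simulated as independent, so false calls from correlation between genes were not covered. Gene Ontology terms printed in the table (1050 terms with 5 to 500 of the 12828 genes) were tested for enrichment among higher and among lower genes with a hypergeometric test over the 11283 genes with a term, adjusted over 8400 tests.

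Named genes were, in each comparison with unfed larvae, the 10 higher and 10 lower genes with the largest fold change among those with an adjusted p under 0.05, a log2 CPM of at least 1 and an assigned symbol, and for each difference the 5 largest each way. For each list they were up to 4 called members with the smallest p and up to 2 called the other way, and 20 genes of lipid handling, the liver, the secretory pathway and the clock were named in any case, of which 1 (creb3l3b) was not found under that symbol. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives that were run and had been planned were a stricter adjusted p of 0.01, a minimum of 2-fold and the overlap among called genes alone. Those chosen after the table was seen were other expression filters, 1 transcript per symbol, recentring on the median fold change, larger standard errors and the stricter list correlation. Other scalings, other test tools, leaving out samples, blocking on the replicate number and other splits of the samples need values of single samples and were not run.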

Results

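Digestive organs were compared between zebrafish larvae that had eaten a high-fat or a low-fat meal 1 h or 4 h earlier and unfed larvae of the same cohort, with 3 pools of 10 larvae in each of the 6 groups. The question was which transcripts a meal moves in the intestine, liver and pancreas, and how fat content and time change the response. All fold changes against unfed larvae are log2 values of the authors' deposited table, in which an adjusted p under 0.05 counts as a call. The table holds no values of single samples, and its implied standard error was about 0.359 for well expressed transcripts. The smallest fold change called lay between 1.15 and 1.41 in the 4 comparisons. The largest changes are named among genes with an assigned symbol and an average log2 CPM of at least 1. The list tests are not the authors' but camera tests run here on the authors' values.

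At 1 h after the high-fat meal, plin2, which codes for a coat protein of lipid droplets, rose by a log2 fold change of 5.54 in the authors' deposited table (adjusted p = 9.2e-33), with an average of 74.6 CPM over all samples. Its transcript ENSDART00000129407 lies on chromosome 15 from 16049488 to 16067837 of Zv9. The authors' deposited table called 719 transcripts higher and 702 lower, and among the 12828 measured genes 252 higher and 227 lower. The largest other rises in the authors' deposited table were those of heat shock genes (hsp70l 2.99), cyp2r1 (3.50), a vitamin D hydroxylase, odc1 (3.48), the first enzyme of polyamine synthesis, ugt5a1 (2.90), abcf2a (2.62) and slc16a6b (2.57). The authors' deposited table also gave 4.70 for hsp70.3;hsp70l, 4.14 for hsp70.2;mcm5 and 4.15 for mcm5. These genes overlap on chromosome 3 from 26878041 to 26953764 and may share reads of the inducible hsp70 copies, so the value of mcm5 is uncertain. Lower genes in the authors' deposited table were led by noxo1b (-3.73), an organizer of an NADPH oxidase, ypel3 (-3.72), rsad2 (-3.45), an antiviral gene, nr0b2a (-3.20), a nuclear receptor of bile acid signalling, cyp24a1 (-3.03), which degrades vitamin D, pdpk1a (-3.01), aqp7 (-2.89), a glycerol channel, the cell death gene bbc3 (-2.82), insig1 (-2.69) and fgf13b (-2.60).

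Genes of lipoprotein assembly and triglyceride synthesis were higher as a list at 1 h after the high-fat meal, with 23 of 29 members above 0. Of 29 measured members 6 were higher and 0 lower (10 and 0 adjusted over the list alone), the median was 0.59, and the camera adjusted p was 1.0e-08. The authors' deposited table gave 3.49 for si:dkey-7f3.15 and 1.35 for zgc:194131 (adjusted p = 2.0e-15 and 0.013), 2 apolipoprotein A-IV genes beside apoa4 on chromosome 16, and 2.88 for zgc:112992, an A-IV paralog on chromosome 19. These paralogs may share reads. apoa4 itself, with 0.59 and an adjusted p of 0.61 in the authors' deposited table, did not pass, nor did apobb (0.68, p = 0.48), the main B apolipoprotein at 1.10e+04 CPM, while apoba (1.21) and the rare apobl (1.4) rose. For mtp, the transfer protein that loads lipid onto apolipoprotein B, the authors' deposited table holds 2 positions on chromosome 1, with 1.18 (adjusted p = 0.045) and 1.13 (adjusted p = 0.063). At 1 h after the low-fat meal these positions had much the same values in the authors' deposited table, 1.16 (adjusted p = 0.048) and 1.07 (adjusted p = 0.082). Among 26 genes of intestinal lipid and sterol transport 3 rose and 1 fell (adjusted p = 0.0012). The authors' deposited table gave 4.27 for nr0b2b, close to 1 CPM on average, 1.27 for slc27a4, a fatty acid transporter, and 1.19 for creb3l3a (adjusted p = 0.044), a transcription factor of hepatocytes and enterocytes, against -3.20 for the paralog nr0b2a.

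Cholesterol synthesis genes were higher at 1 h after the high-fat meal. Of 26 members 5 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.69 and a list adjusted p of 2.3e-06. In the authors' deposited table hmgcs1, the synthase before HMG-CoA reductase, rose by 2.22, the squalene epoxidase gene sqlea by 1.96 and mvk by 1.45. The exception was insig1, a sterol-dependent brake on the pathway. The authors' deposited table gave 1.16 for hmgcra (adjusted p = 0.052), 0.13 for srebf2 (p = 1) and -0.27 for ldlr (p = 1), none of which passed. Endoplasmic reticulum chaperones had 10 of 35 members higher and 0 lower (12 and 0 adjusted over the list alone, list adjusted p = 2.5e-10). Examples in the authors' deposited table were hspa5 (2.54), the main luminal chaperone, its cofactors dnajb9a (2.53) and dnajb9b (2.34), and pdia4 (1.82). Cytosolic heat shock genes had 6 of 27 members higher and 0 lower (list adjusted p = 4.8e-06), among them dnajb1b (2.51), bag3 (2.07) and hsp90aa1.2 (1.52) in the authors' deposited table.

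Some fasting genes fell at 1 h after the high-fat meal: of 24 genes of gluconeogenesis and fasting hormones 7 were lower and 0 higher over all genes (9 and 2 adjusted over the list alone). The list median was -0.18, with 11 members above 0, and the list adjusted p was 0.0033 by camera on the authors' values. In the authors' deposited table igfbp1a fell by 2.1, the insulin-repressed binding protein igfbp1b by 1.71, sesn1 by 1.85 and the ubiquitin ligase gene trim63 by 1.79, whereas pck1, the gluconeogenic carboxykinase, had 0.43 and did not pass (adjusted p = 0.87). Among 33 inflammation genes 3 were lower, cxcl-c1c (-2.37), steap4 (-2.04) and nfkb2 (-1.38) in the authors' deposited table (list adjusted p = 0.0024). Immediate early genes gave 4 higher and 0 lower of 31, with nr4a3 (2.42), atf3 (1.62), jun (1.6) and fosb (1.55) in the authors' deposited table, but the list did not pass (adjusted p = 0.098). Skeletal muscle genes, markers of tissue outside the dissected organs, lay lower as a list (median -0.68, 3 of 30 called lower, list adjusted p = 6.4e-10) by camera on the authors' values. Markers of exocrine pancreas (median -0.16, p = 0.31), liver (-0.02, p = 0.94) and smooth muscle (-0.09, p = 0.64) did not pass by camera on the authors' values. Lists that also passed by camera on the authors' values were fatty acid oxidation (1 of 33 higher, median 0.32, p = 3.7e-04), protein translocation (1 of 47 higher, p = 7.1e-04) and enterocyte markers (2 of 25 higher, p = 0.0043). The median of the enterocyte markers lay at percentile 94.09 of random lists matched on expression. Calls of ribosome biogenesis (3 of 73 higher, p = 0.0093), glucocorticoid targets (4 of 24 lower, p = 0.0092), clock genes (2 higher and 4 lower of 38, p = 0.0090) and fatty acid synthesis (1 of 23 higher, p = 0.024) were lost at a list correlation of 0.05, with adjusted p of 0.16, 0.074, 0.10 and 0.12. Lipid transport was the enriched Gene Ontology term of lipid genes (7 of 33 genes higher, hypergeometric adjusted p = 0.0058). Its higher genes included si:dkey-7f3.15, zgc:112992, zgc:194131 and apobl of the lipoprotein list, so the term is no separate support.

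At 4 h after the high-fat meal plin2 was still higher, by 4.33 in the authors' deposited table (adjusted p = 1.8e-21), and genes of fatty acid oxidation were higher as a list. Of 33 genes of fatty acid oxidation and PPAR-alpha targets 5 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.53 and a list adjusted p of 1.1e-15. The authors' deposited table gave 2.86 for cpt1b, a carnitine palmitoyltransferase of mitochondrial import, 2.60 for hadhaa, of the mitochondrial trifunctional protein, and 1.71 for angptl4, an inhibitor of lipoprotein lipase, whereas cpt1a had 0.52 and did not pass (adjusted p = 0.98). The list was already higher at 1 h, and its difference between 4 h and 1 h did not pass (adjusted p = 0.062 by camera on differences of the authors' values). In all, the authors' deposited table called 258 transcripts higher and 283 lower, or 95 and 79 genes. Other large rises in the authors' deposited table were rsad2 (3.69), the interferon-induced mxa (3.62) and mxe (2.55), the transcription factor klf11b (3.0), the fatty acid elongase elovl5 (2.43), clec19a (2.22) and fam114a1 (2.21). The largest falls in the authors' deposited table were rhcga (-3.99), an ammonia transporter, nr1d4b (-3.95) of the Rev-erb receptor family, the cell cycle inhibitor cdkn1a (-2.72), obsl1b (-2.37), col2a1a (-2.19), myhz1.2 (-2.12), the phosphate transporter slc34a2a (-2.10), dhrs13a.2 (-2.04), the clock gene per1a (-1.96) and nr4a1 (-1.91).

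**Figure D1:**
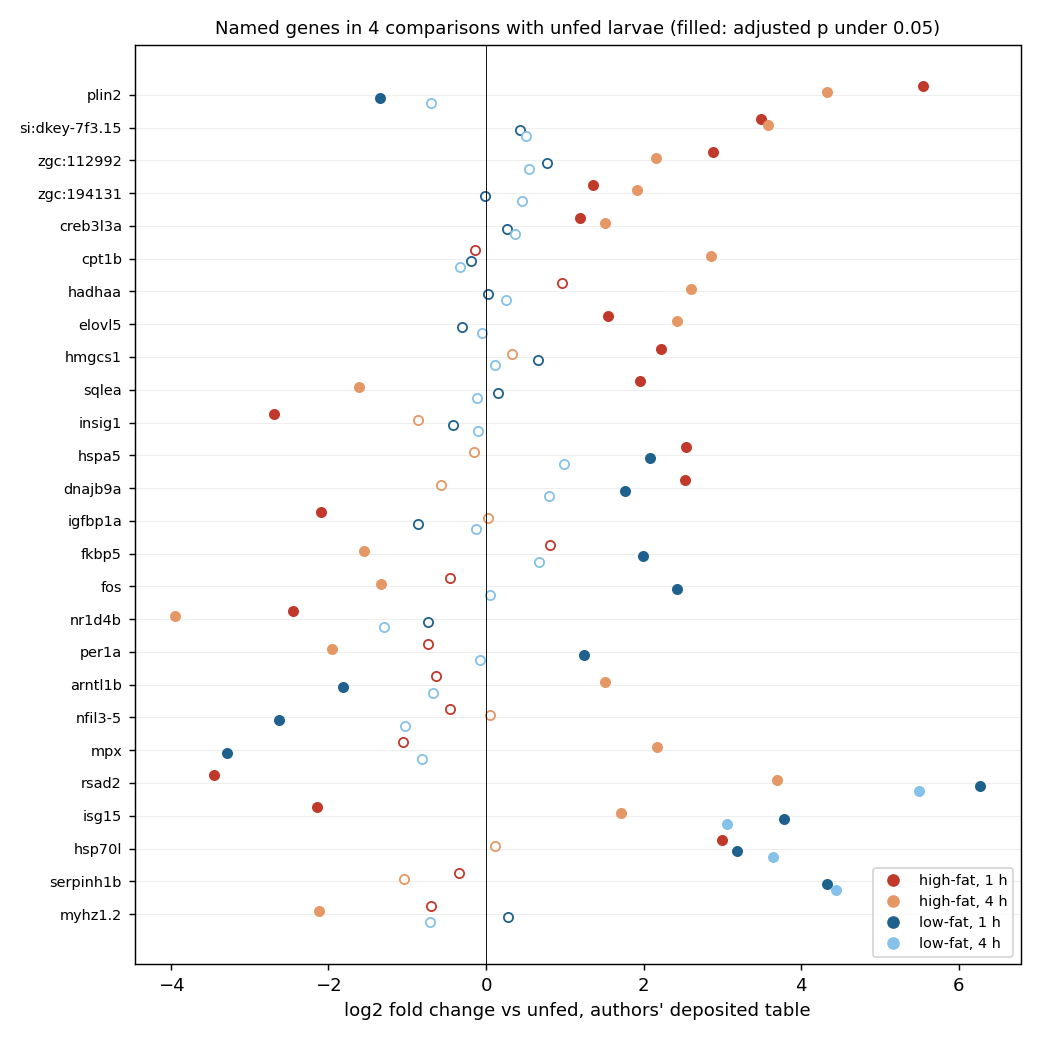
Log2 fold changes against unfed larvae of 26 named genes in the authors' deposited table, 1 point per comparison (high-fat 1 h and 4 h, low-fat 1 h and 4 h), filled where the adjusted p was under 0.05. plin2 and the apolipoprotein A-IV genes si:dkey-7f3.15, zgc:112992 and zgc:194131 lay to the right at both times after the high-fat meal, while rsad2 lay at -3.45 at 1 h and at 3.69 at 4 h after that meal.

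The lipoprotein list was again higher at 4 h after the high-fat meal (5 higher and 2 lower of 29, 8 and 2 adjusted over the list alone, list adjusted p = 1.1e-07). Its median was 0.19, against 0.59 at 1 h. The authors' deposited table gave 3.58 for si:dkey-7f3.15, 2.15 for zgc:112992, 1.92 for zgc:194131 and 1.93 for apoea, an apolipoprotein E gene, against -1.56 for the phosphatidate phosphatase gene lpin1 and -1.53 for apobl, which had been higher at 1 h. Lipoprotein metabolic process was an enriched Gene Ontology term, with 5 of 12 genes higher (hypergeometric adjusted p = 1.1e-04). These were apoeb and the higher genes just named, so the term is no separate support. In lipid transport 4 of 26 genes rose and 0 fell, which were nr0b2b (5.00), creb3l3a (1.51), the bile acid binding protein gene fabp6 (1.47) and fabp1b.1 (1.34) in the authors' deposited table. That list's adjusted p was 0.015, and 0.087 at a list correlation of 0.05. Its median lay at percentile 79.53 of random lists matched on expression, which is not extreme. The authors' deposited table gave no call for pla2g12b (0.77, adjusted p = 0.54), fabp2 (0.43, p = 1), the liver fabp10a (-0.37, p = 1) or srebf1 (-0.08, p = 1). In fatty acid synthesis elovl5 and me1 (2.14), of NADPH supply, rose in the authors' deposited table and fasn, near 1 CPM, had -1.18 (adjusted p = 0.18), while the list did not pass (adjusted p = 0.17).

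Cholesterol synthesis had the opposite sign at 4 h after the high-fat meal, with 0 of 26 genes higher and 3 lower (0 and 4 adjusted over the list alone), a median of -0.45 and a list adjusted p of 5.5e-07. In the authors' deposited table lss, the cyclase that forms lanosterol, fell by 1.69, sqlea by 1.61 and mvda by 1.46. Targets of glucocorticoids were lower (0 higher and 3 lower of 24, median -0.72, list adjusted p = 9.3e-13), with fkbp5 (-1.55), ddit4 (-1.46) and per1a in the authors' deposited table. Of these 24 genes 8 are in another list as well. The clock list also holds per1a, so these 2 lists are not fully separate results. Of 38 clock genes 6 fell and 1 rose (12 and 9 adjusted over the list alone, list adjusted p = 0.0019). The authors' deposited table gave, besides nr1d4b and per1a, -1.70 for dbpb and -1.56 for nr1d1, and 1.51 for arntl1b, a Bmal1 gene, while per3 had -0.44 and did not pass. Skeletal muscle genes were lower as a list (7 of 30 called, 28 adjusted over the list alone, median -1.04, adjusted p = 1.0e-33), led in the authors' deposited table by myhz1.2, ttnb (-1.70), myhz1.1 (-1.60) and ttna (-1.56). Lysosome rich enterocyte genes gave 2 of 30 higher (adjusted p = 2.8e-05), cubn (1.85), of protein uptake, and fabp6 in the authors' deposited table, and proteasome subunits had a median of 0.32 with 0 of 46 called (adjusted p = 1.8e-04). Endoplasmic reticulum chaperones (p = 0.17), heat shock genes (p = 0.56) and ribosome biogenesis (p = 0.90) had 0 called members and did not pass by camera on the authors' values. Immediate early genes (2 of 31 lower, median -0.25, p = 1.2e-04) and blood genes (0 of 12 called, -0.28, p = 0.0046) lay lower by camera on the authors' values, and protein translocation (0 of 47 called, 0.28, p = 9.7e-07) higher. Calls lost at a list correlation of 0.05 were fasting genes (p = 0.011, then 0.074), liver markers (0.011, then 0.087), ribosomal proteins (0.022, then 0.20), goblet cells (0.023, then 0.054) and skin, eye and nervous tissue (0.030, then 0.11).

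At 1 h after the low-fat meal antiviral genes, heat shock genes and cyp2r1 had the largest rises. The authors' deposited table gave 6.27 for rsad2 (adjusted p = 1.4e-37; ENSDART00000019617, chromosome 17 from 35524581 to 35528452), 5.1 for mxe, 4.68 for cmpk2, 4.31 for stat1b, 4.25 for mxa, 3.78 for isg15 and 3.68 for ifit2, all induced by interferon. Other large rises there, again in the authors' deposited table, were cyp2r1 (5.03), serpinh1b (4.33), a collagen chaperone, and hsp70.2;mcm5 (3.95). Calls numbered 1031 transcripts higher and 576 lower in the authors' deposited table, or 349 and 172 genes. Lower genes in the authors' deposited table were noxo1b (-3.82), mpx (-3.29), the neutrophil myeloperoxidase, nfil3-2 (-2.92), ypel3 (-2.83), crtac1a (-2.80), nfil3-5 (-2.63), klf11a (-2.40), rnf183 (-2.37), il1b (-2.37), an inflammatory cytokine, and the epithelial factor elf3 (-2.32).

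Immediate early genes rose at 1 h after the low-fat meal, with 11 higher and 0 lower of 31 (13 and 0 adjusted over the list alone), a median of 0.65 and a list adjusted p of 6.8e-10. Examples in the authors' deposited table were fos (2.42), nr4a3 (2.43), fosb (2.35) and egr1 (1.75). Heat shock genes (8 of 27 higher, 0 lower, p = 5.1e-08) included hsp70l (3.19), dnajb1b (3.06) and dnaja1 (2.44), and endoplasmic reticulum chaperones (7 of 35 higher, 0 lower, p = 2.2e-07) included hspa5 (2.08), creld2 (2.15), pdia4 (1.71) and dnajb9a (1.76) in the authors' deposited table. Ribosome biogenesis rose (7 of 73 higher, 13 adjusted over the list alone, 0 lower, median 0.46, p = 2.2e-07), with dkc1 (1.79), rrs1 (1.65), dimt1l (1.48) and nop2 (1.44) in the authors' deposited table. In enterocyte markers 3 of 25 rose (p = 5.6e-05), which were elovl7b (3.06), slc6a19a (1.56), a transporter of neutral amino acids, and sult1st1 (1.32) in the authors' deposited table. For sterol and lipid transport 4 of 26 rose and 1 fell, among them npc1l1 (1.87), of cholesterol uptake, abcb11a (1.47), the bile salt pump, abca1b (1.36) and slc27a4 (1.36) in the authors' deposited table. That list's adjusted p was 0.0039, and 0.052 at a list correlation of 0.05.

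Inflammation genes fell at 1 h after the low-fat meal (0 higher and 5 lower of 33, list adjusted p = 2.9e-04), and so did leukocyte markers (0 and 2 of 18, median -0.37, p = 1.6e-04), by camera on the authors' values. Of the inflammation genes 11, and of the leukocyte markers 6, are in another list as well. Both lists hold mpx, so they are not separate results. The authors' deposited table gave, besides mpx and il1b, -1.60 for irg1l, -1.34 for nfkb2 and -1.26 for mmp13a. Clock genes had 2 higher and 9 lower of 38 (list adjusted p = 4.4e-04): nfil3-5, arntl1b (-1.82), arntl1a (-1.67) and cry4 (-1.64) fell, and per1a (1.25) and dbpa (1.25) rose, in the authors' deposited table. Glucocorticoid targets, which include per1a of the clock list, rose with 4 of 24 higher. Among them were fkbp5 (2.0), pik3r3a (1.47) and ddit4 (1.33) in the authors' deposited table. That list's adjusted p was 0.025, and 0.13 at a list correlation of 0.05. Besides lipid transport, the lipid lists did not pass at 1 h after the low-fat meal: lipoprotein assembly (median 0.22, p = 0.12), fatty acid oxidation (0.03, p = 0.95), cholesterol synthesis (0.15, p = 0.51) and fatty acid synthesis (-0.01, p = 0.53), by camera on the authors' values. Single lipid genes that fell in the authors' deposited table were plin2 (-1.34), the desaturase gene scd (-2.21) and me1 (-1.30). Skeletal muscle genes had a median of 0.28 and did not pass (p = 0.13 by camera on the authors' values). Calls lost at a list correlation of 0.05 also included protein translocation (p = 0.025, then 0.18), lysosome rich enterocytes (0.025, then 0.15) and blood (0.037, then 0.13).

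At 4 h after the low-fat meal few genes were called against unfed larvae: the authors' deposited table called 143 transcripts higher and 36 lower, or 56 genes higher and 1 lower. In this comparison 2.39% of well expressed genes had an unadjusted p under 0.05. The shared error may thus be too large here, and few calls need not mean a small response. Normal scores of well expressed genes had a robust SD of 0.526, against 0.930 at 1 h after the low-fat meal. The list test weighs a list against the spread over all genes. List p-values here are therefore not comparable in size with those of other comparisons. The largest rises in the authors' deposited table were again rsad2 (5.49), serpinh1b (4.44), cmpk2 (4.37), mxe (4.03), stat1b (3.77), hsp70l (3.64) and mxa (3.49), with 4.73 for hsp70.2;mcm5, 3.98 for hsp70.3;hsp70l and 4.02 for the uncertain mcm5. The lower gene was paics (-1.75) of purine synthesis in the authors' deposited table. Heat shock genes had 5 of 27 higher and 0 lower (9 and 0 adjusted over the list alone, list adjusted p = 6.3e-26), including hsp90aa1.2 (2.84) and dnajb1b (2.24) in the authors' deposited table. Endoplasmic reticulum chaperones (1 of 35 higher, pdia4 with 1.42 in the authors' deposited table, median 0.39, p = 2.8e-10) and ribosome biogenesis (0 of 73 called, median 0.38, p = 2.8e-10) moved as lists. Clock genes (0 of 38 called, median -0.19, p = 9.6e-07) and leukocyte markers (0 of 18 called, median -0.23, p = 0.0045) lay lower as lists by camera on the authors' values, as did lysosome rich enterocytes (0 of 30 called, -0.24, p = 4.8e-04). Lost at a list correlation of 0.05 were protein translocation (p = 0.0032, then 0.099), exocrine pancreas (0.032, then 0.18), liver (0.035, then 0.20) and blood (0.035, then 0.12). Cholesterol synthesis (0.04, p = 0.82), fatty acid oxidation (-0.05, p = 0.54) and lipoprotein assembly (0.10, p = 0.39) did not pass by camera on the authors' values.

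**Figure D2:**
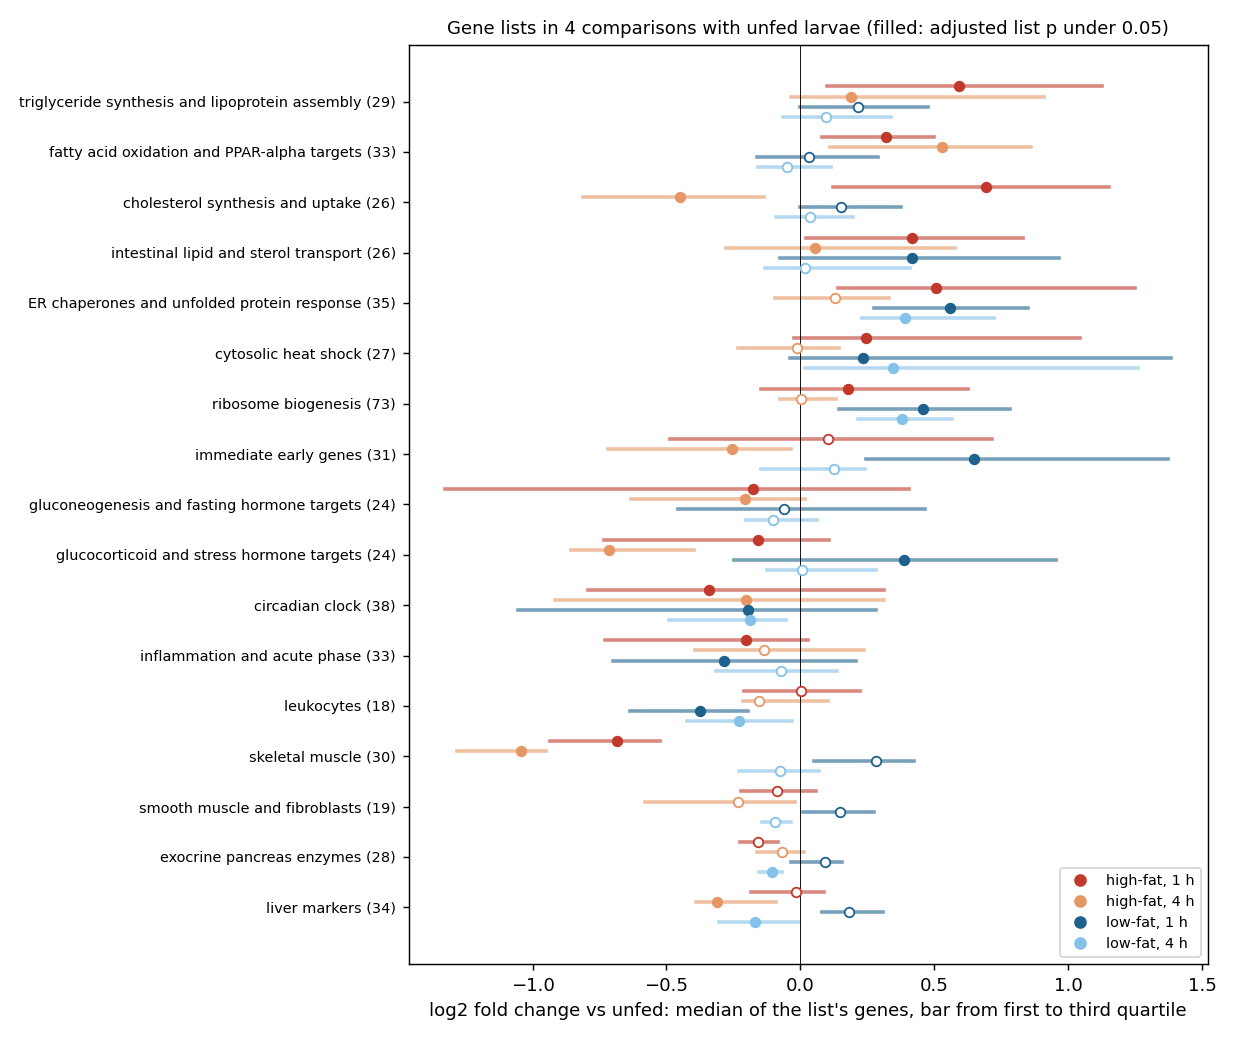
Median log2 fold change against unfed larvae of 17 gene lists in 4 comparisons, with bars from the first to the third quartile of the members, the number of measured members in parentheses, and filled points where the camera adjusted p was under 0.05. Cholesterol synthesis had a median of 0.69 at 1 h and -0.45 at 4 h after the high-fat meal, and skeletal muscle genes had medians of -0.68 and -1.04.

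The 2 meals were compared by the difference between them, each against its own unfed larvae. They were different foods (5% egg yolk emulsion and 10% egg white), so the difference is not one of fat content alone. Since meal and cohort coincide, this difference includes any difference between the cohorts. At 1 h the approximate test called 28 genes higher after the high-fat meal and 98 lower. The largest differences computed from the authors' deposited table were plin2 (6.88), klf11a (2.88), hmox1a (2.58), heme oxygenase, klf11b (2.56) and the linker histone gene histh1l (2.36), and on the other side rsad2 (-9.72), isg15 (-5.92), cmpk2 (-5.85), ifit2 (-5.08) and stat1b (-4.86). By camera on differences of the authors' values, cholesterol synthesis (median difference 0.50, p = 3.0e-04), lipoprotein assembly (0.17, p = 1.5e-04), fatty acid oxidation (0.21, p = 1.5e-04) and fatty acid synthesis (0.32, p = 0.0033) were higher after the high-fat meal. Glucocorticoid targets (-0.68, p = 1.0e-06) and immediate early genes (-0.26, p = 1.8e-05) were lower by camera on differences of the authors' values. Endoplasmic reticulum chaperones (0.00, p = 0.38) and heat shock genes (-0.07, p = 0.22) did not differ past the threshold, by camera on differences of the authors' values. Cell type markers differed as well by that test on the authors' values, with leukocytes higher (0.38, p = 7.4e-04) and blood (-0.64, p = 0.015, and 0.053 at a list correlation of 0.05) and skin, eye and nervous tissue (-0.38, p = 0.0059) lower after the high-fat meal.

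At 4 h 30 genes were higher and 37 lower after the high-fat than after the low-fat meal. The largest differences computed from the authors' deposited table were plin2 (5.03), cpt1b (3.19), klf11b (3.17), mpx (2.98) and klf11a (2.53), against serpinh1b (-5.48), hsp70.2;mcm5 (-5.38), cmpk2 (-4.27), hsp70.3;hsp70l (-3.96) and hsp90aa1.2 (-3.83). Fatty acid oxidation genes were higher after the high-fat meal (4 of 33 called, median 0.66, p = 1.3e-16), as were lysosome rich enterocyte genes (median 0.54, p = 4.0e-11), by camera on differences of the authors' values. By that test on the authors' values heat shock (5 of 27 lower, p = 1.7e-17), cholesterol synthesis (-0.53, p = 1.7e-06) and ribosome biogenesis (-0.37, p = 3.2e-05) were lower. Skeletal muscle genes lay lower after the high-fat meal at both times (-0.87 and -1.03), beside all of these lists.

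The responses to the 2 meals overlapped at both times. Across 12828 genes, which are not independent replicates, the log2 fold changes after both meals had a Pearson r of 0.50 and a Spearman rho of 0.53 at 1 h, and 0.31 and 0.27 at 4 h. At 1 h 100 genes were higher after both meals, where independent lists would share 6.86, and 62 were lower after both, against 3.04. 1 gene was higher after the high-fat and lower after the low-fat meal, against 3.38 for independent lists, and 9 the reverse, against 6.18. Genes shared at 1 h included hspa5, cyp2r1 and odc1 among the higher and noxo1b, ypel3, cyp24a1 and igfbp1b among the lower. At 4 h 28 genes, rsad2, mxa and mxe among them, were higher after both meals, against 0.415, and 0 were lower after both, against 0.00616. At that time 1 gene was lower after the high-fat and higher after the low-fat meal, against 0.345, and 0 the reverse. The shared higher genes were 100 of 252 high-fat and of 349 low-fat higher genes at 1 h, and 28 of 95 and of 56 at 4 h. Of high-fat calls, 87.3% at 1 h and 64.9% at 4 h had the same sign after the low-fat meal, and of low-fat calls 85% and 80.7% had the same sign after the high-fat meal.

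**Figure D3:**
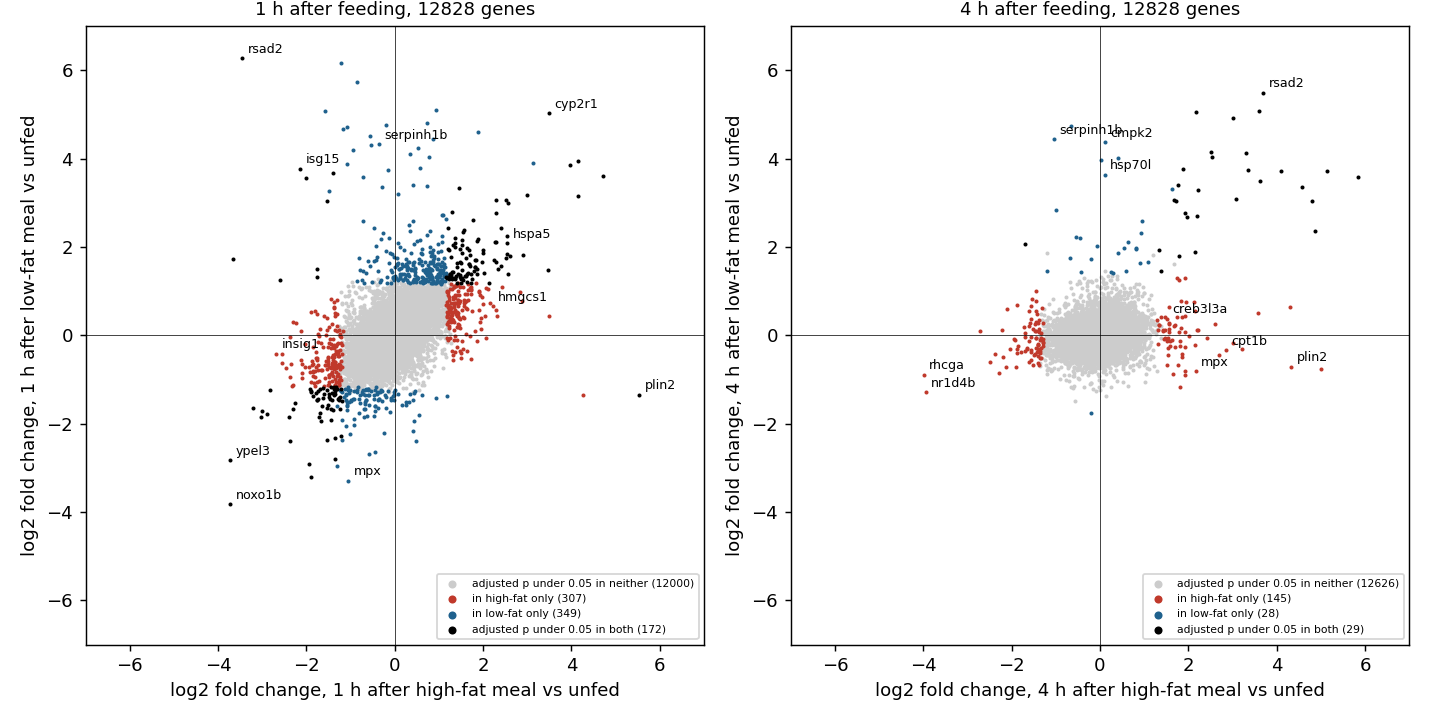
Log2 fold change after the low-fat meal (vertical axis) against that after the high-fat meal (horizontal axis), each against unfed larvae, at 1 h (left) and 4 h (right), 1 point per gene for 12828 genes, coloured by where the authors' adjusted p was under 0.05. Points spread along the diagonal at 1 h (r = 0.50) and less so at 4 h (r = 0.31), with plin2 far to the right at both times.

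Time after the meal was addressed by the difference between 4 h and 1 h, in which the unfed larvae cancel. Each cohort had a single unfed group, and the labels give no time for it. The difference thus includes any change with clock time or handling, which cannot be told apart from the course of the meal. After the high-fat meal 420 genes were higher and 416 lower at 4 h by the approximate test. The largest differences computed from the authors' deposited table were rsad2 (7.14), noxo1b (5.03), ypel3 (4.41), isg15 (3.86) and helz2 (3.56), against hsp70.2;mcm5 (-4.79), hsp70.3;hsp70l (-4.68), rhcga (-4.42), cdkn1a (-4.35) and the uncertain mcm5 (-3.74). Cholesterol synthesis was lower at 4 h (11 of 26 lower, 1 higher, median -0.87, p = 3.3e-15, camera on differences of the authors' values). By that test on the authors' values lower lists also included endoplasmic reticulum chaperones (7 of 35, p = 6.3e-06), heat shock genes (7 of 27, p = 6.3e-06), immediate early genes (6 of 31, p = 2.0e-05) and enterocyte markers (6 of 25 lower, 1 higher, p = 1.3e-04). Skeletal muscle genes were lower too (median -0.42, 26 of 30 below 0, p = 0.016 by camera on differences of the authors' values, and 0.16 at a list correlation of 0.05). After the low-fat meal 80 genes were higher and 180 lower at 4 h. The largest differences computed from the authors' deposited table were noxo1b (3.63), clec19a (2.55), mpx (2.48), ypel3 (2.39) and scd (2.33), against rhcga (-4.30), cyp2r1 (-3.05), fosb (-2.97), dhrs13a.2 (-2.95) and elnb (-2.57). Immediate early genes (8 of 31, p = 1.6e-14) and enterocyte markers (3 of 25, p = 2.0e-06) were lower at 4 h, and inflammation genes higher (4 higher and 1 lower of 33, p = 0.0011), by camera on differences of the authors' values. Markers of the liver, a dissected organ, and of other tissues were lower too by that test on the authors' values: blood (median -0.73, p = 1.9e-05), liver (-0.36, p = 7.4e-04), skin, eye and nervous tissue (-0.33, p = 2.8e-04) and skeletal muscle (-0.27, p = 5.8e-04). Leukocyte markers were higher (median 0.21, 13 of 18 above 0, p = 0.015 by camera on differences of the authors' values, and 0.078 at a list correlation of 0.05).

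Comparisons of 1 h and 4 h with the same unfed libraries share chance values. After the high-fat meal the log2 fold changes at 1 h and 4 h had an r of 0.26 across genes, where simulated groups without effect gave 0.50, and a covariance of 0.066 against 0.068. After the low-fat meal r was 0.61 and the covariance 0.12 against 0.068. 54 genes, led by rsad2, were then higher at both times, where independent lists would share 1.52 and simulated groups 0.06. After the high-fat meal 22 genes, plin2 among them, were higher at both times (1.87 for independent lists, 0.22 simulated) and 5 lower (1.4 and 0.165). Part of any excess may come from the shared unfed libraries. The simulated groups used the implied standard errors, which may be too large, so their values are no firm baseline.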

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

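All tests in this part were chosen after the results were seen, apart from the gene lists, which were fixed before unless named otherwise. Among genes with an assigned symbol and an average log2 CPM of at least 1, the largest of the differences between the meals called by the approximate test (126 genes at 1 h and 67 at 4 h in all) were, at 1 h, plin2 (6.88), klf11a (2.88), hmox1a (2.58), klf11b (2.56) and histh1l (2.36), and rsad2 (-9.72), isg15 (-5.92), cmpk2 (-5.85), ifit2 (-5.08) and stat1b (-4.86). At 4 h the largest were plin2 (5.03), cpt1b (3.19), klf11b (3.17), mpx (2.98) and klf11a (2.53), and serpinh1b (-5.48), hsp70.2;mcm5 (-5.38), cmpk2 (-4.27), hsp70.3;hsp70l (-3.96) and hsp90aa1.2 (-3.83). The less expressed nr0b2b, outside that filter, differed by 5.62 at 1 h and 5.75 at 4 h. Values are high-fat minus low-fat log2 fold changes computed from the authors' deposited table.

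Gene lists differed between the meals as well. At 1 h higher medians after the high-fat meal were found for cholesterol synthesis (0.50), leukocytes (0.38), lysosome rich enterocytes (0.37), fatty acid synthesis (0.32), proteasome subunits (0.23), fatty acid oxidation (0.21) and lipoprotein assembly (0.17). Lower medians at 1 h were those of skeletal muscle (-0.87), glucocorticoid targets (-0.68), blood (-0.64), skin, eye and nervous tissue (-0.38), ribosome biogenesis (-0.29), immediate early genes (-0.26) and fasting genes (-0.11). At 4 h the higher lists were fatty acid oxidation (0.66), lysosome rich enterocytes (0.54), proteasome subunits (0.27), lipoprotein assembly (0.11), leukocytes (0.11), protein translocation (0.090) and lipid transport (0.054). The lower lists at 4 h were skeletal muscle (-1.03), glucocorticoid targets (-0.76), cholesterol synthesis (-0.53), immediate early genes (-0.43), ribosome biogenesis (-0.37), endoplasmic reticulum chaperones (-0.22) and heat shock genes (-0.15). At a list correlation of 0.05, ribosome biogenesis, proteasome subunits, fasting genes and blood no longer passed at 1 h. The same held at 4 h for leukocytes, protein translocation, lipid transport, chaperones of the endoplasmic reticulum and proteasome subunits. Among random lists matched on expression, the median of fasting genes at 1 h lay at percentile 21.49. At 4 h the medians of lipid transport, leukocytes and heat shock genes lay at percentiles 91.74, 93.05 and 5.44. These medians by themselves were thus not extreme.

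With the same filter, the largest differences between 4 h and 1 h after the high-fat meal were rsad2 (7.14), noxo1b (5.03), ypel3 (4.41), isg15 (3.86) and helz2 (3.56), and hsp70.2;mcm5 (-4.79), hsp70.3;hsp70l (-4.68), rhcga (-4.42), cdkn1a (-4.35) and mcm5 (-3.74), computed from the authors' deposited table. After the low-fat meal they were noxo1b (3.63), clec19a (2.55), mpx (2.48), ypel3 (2.39) and scd (2.33), and rhcga (-4.30), cyp2r1 (-3.05), fosb (-2.97), dhrs13a.2 (-2.95) and elnb (-2.57).

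Interferon response genes, a list of 30 measured textbook genes put together after the table was seen, had medians of 1.31 and 0.95 at 1 h and 4 h after the low-fat meal, and of -0.27 and 0.44 after the high-fat meal. Unfed libraries of the high-fat cohort that are high in these genes, as the whole cause, would leave no difference between 4 h and 1 h after that meal, yet 15 of 30 were higher at 4 h, against 0.982 by share. After the low-fat meal the list was lower at 4 h than at 1 h (median -0.38, bootstrap SD over genes 0.095, camera p = 0.0048 at a list correlation of 0.05), which low unfed libraries of that cohort would not give, although single genes that were lower numbered 2 of 30. The list was drawn up after large values of such genes were seen in these comparisons. Neither that p-value nor the count of 15 is therefore independent support. For the level at 4 h after the low-fat meal, where 13 of 30 were higher than in unfed larvae, low unfed libraries cannot be told apart from a lasting response, since both would give it. The response of a single pool or clutch and an effect of the meals stay open as well, because values of single samples were not analysed here.

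Clock genes moved apart in 2 of the 4 comparisons with unfed larvae, in 2 arms of 13 per, nr1d, dbp, tef and hlf genes and of 9 arntl, clock, npas2 and nfil3 genes, which were split after the table was seen. The arms had medians of -1.17 and 0.99 at 4 h after the high-fat meal, a gap of 2.16 that argues against scaling of the libraries there, and of 0.24 and -1.46 at 1 h after the low-fat meal. Both arms lay below 0 at 1 h after the high-fat meal (-0.32 and -0.46) and at 4 h after the low-fat meal (-0.07 and -0.54). Unfed larvae taken at another clock time in each cohort is a candidate explanation: where the unfed libraries cancel, the 4 h minus 1 h differences of the 38 clock genes went the same way after both meals (r = 0.82), although r against unfed larvae was 0.15 at 1 h and -0.12 at 4 h. Random lists matched on expression had a median r of 0.68 for the same difference, and the clock list lay at their percentile 87.4, so this test does not single out the clock and the sampling time cannot be told apart from an effect of the meals.

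Skeletal muscle genes lay lower after the high-fat meal, by a median of -0.68 at 1 h and -1.04 at 4 h, and not after the low-fat meal (0.28 and -0.07). Muscle and the skin, eye and nervous tissue list did not fall alike at 4 h. Muscle lay below that list by a median difference of -0.74. This argues against an equal loss of all adhering body wall and head tissue only if these genes mark that tissue alone. That was not tested. The skin, eye and nervous tissue list itself lay lower at 4 h (median -0.30, 14 of 19 below 0), so an unequal loss stays open. At 1 h the difference was -0.29, against a bootstrap SD over genes of 0.28 for that list. There an equal loss stays open as well. Less body-wall muscle left on the dissected organs cannot be told apart from a change within muscle: 29 of 30 muscle genes lay below 0 at 4 h, as both would give, and their SD of 0.43 exceeded those of the same genes after the low-fat meal (0.28 and 0.26). The comparisons at 1 h and 4 h share their unfed libraries. Unfed pools of the high-fat cohort with more muscle would lower the list at both times. Where those libraries cancel, the median 4 h minus 1 h difference was -0.42 after the high-fat meal and -0.27 after the low-fat meal. The former had a camera adjusted p of 0.016, and 0.16 at the stricter list correlation. Such unfed pools stay open for the level at both times. An effect of the meal on muscle was not tested and stays open.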

How the results depend on the processing

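Only the stricter adjusted p, the 2-fold minimum and the overlap among called genes were planned before the data were examined; all other alternatives were chosen after seeing them. No paired analysis was possible because the authors' deposited table compares groups and values of single samples were not used, so replicate numbers could not enter a fit. For the same reason other scalings, other test tools, no expression filter on counts, fits within a cohort, leaving out each replicate, an estimated list correlation, fry and other splits of the samples were not run. A limit is that the authors' p-values rest on a spread shared by all transcripts.

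At an adjusted p under 0.01, 716 transcripts were called at 1 h and 308 at 4 h after the high-fat meal, and 945 at 1 h after the low-fat meal, from 1421, 541 and 1607. That threshold gave 76 genes for the meal difference at 1 h (from 126), 494 for 4 h against 1 h after the high-fat meal (from 836) and 129 after the low-fat meal (from 260). With standard errors 1.5 times as large the 4 comparisons with unfed larvae called 113, 51, 206 and 63 transcripts (high-fat 1 h and 4 h, low-fat 1 h and 4 h), the meal differences 38 and 16 genes at 1 h and 4 h, and the time differences 157 and 29 genes after the high-fat and the low-fat meal. With only transcripts of log2 CPM of at least 0, which removes tests, 118 instead of 179 were called at 4 h after the low-fat meal. With a filter at log2 CPM of at least 2 the meal differences called 76 and 41 genes (from 126 and 67) and the time differences 552 and 159, since fewer genes were tested. The meals' correlation at 4 h was 0.41 among called genes; the cause was not tested. At a list correlation of 0.05 the lists that passed were 11 of 17 at 4 h after the high-fat meal, 8 of 13 and 6 of 10 at 1 h and 4 h after the low-fat meal, 9 of 14 for the meal difference at 4 h and 5 of 9 for 4 h against 1 h after the high-fat meal.

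The 2-fold minimum removed no call in any of the 8 comparisons, since the implied errors already set a larger minimum. Recentring on the median fold change changed none of the 16 counts by more than 1.5 times. It ended a call in 1 of 240 list results, blood at 1 h after the low-fat meal (adjusted p = 0.051), where 12 instead of 13 lists passed. No named gene, list, count or correlation changed its direction under an alternative that was run. Most alternatives leave the fold changes of genes as they are and recentring shifts all genes alike, so this is hardly a test of direction. Of 271 named values against unfed larvae 42 ended at an adjusted p under 0.01, and with larger standard errors 127 of 311 ended. hmgcra (adjusted p = 0.036) and mtp (adjusted p = 0.043) at 1 h after the high-fat meal passed with only transcripts of log2 CPM of at least 0.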

Other observations

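The genes of this part were picked after their values were seen. 2 genes of vitamin D handling moved at 1 h after both meals: in the authors' deposited table cyp2r1, which activates vitamin D and whose row overlaps calca, rose by 3.50 after the high-fat and 5.03 after the low-fat meal, and cyp24a1, which degrades vitamin D, had -3.03 and -1.85. At 4 h after the high-fat and the low-fat meal the authors' deposited table gave -0.43 and -0.53 for cyp24a1, with no call, and 0.83 and 1.98 for cyp2r1, called after the low-fat meal alone (adjusted p = 0.010). The phosphate transporter slc34a2a and the ammonia transporter rhcga had 2.72 and 3.41 at 1 h after the low-fat meal and -2.10 and -3.99 at 4 h after the high-fat meal in the authors' deposited table, while their values at 1 h after the high-fat meal (1.07 and 0.42) did not pass. From 1 h to 4 h rhcga fell after the low-fat meal as well (difference -4.30). The myeloperoxidase gene mpx had -1.05 (not passed) and 2.17 at 1 h and 4 h after the high-fat meal, and -3.29 and -0.81 (not passed) at 1 h and 4 h after the low-fat meal, in the authors' deposited table.

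The change from 1 h to 4 h was alike in part after the 2 meals, although no libraries are shared between these differences. Both differences include any change with clock time. Immediate early genes fell after both meals (medians -0.57 after the high-fat and -0.51 after the low-fat meal). In the same order, cholesterol synthesis (-0.87 and -0.12) and interferon genes (0.98 and -0.38) differed. Heat shock genes had 7 of 27 lower after the high-fat and 0 after the low-fat meal. Across 12828 genes r was 0.57 and rho 0.62, above the r of 0.50 at 1 h and 0.31 at 4 h against unfed larvae. 53 genes, noxo1b and ypel3 among them, were higher at 4 h after both meals, where independent lists would share 2.62, and 87, rhcga among them, were lower, against 5.84. 7 genes went opposite ways, but the number under independent lists was not computed for them, so this count does not show agreement. The meal difference itself had an r of 0.52 between 1 h and 4 h, against 0.50 for simulated groups without effect that share their unfed libraries, with a covariance of 0.14 in both the data and the simulation. That simulation used the implied standard errors, which may be too large, so it is no firm baseline. The like values therefore do not show that no difference between the meals lasted.

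Calls among markers of the dissected organs were counted by list, with no test between lists. Enterocyte markers had 2 of 25 higher at 1 h and 2 lower at 4 h after the high-fat meal and 3 higher at 1 h after the low-fat meal. Lysosome rich enterocyte genes had 2 higher and 1 lower of 30 at 1 h and 2 higher at 4 h after the high-fat meal, and 0 called after the low-fat meal. Exocrine pancreas enzymes had medians of -0.16, -0.07, 0.09 and -0.10 at 1 h and 4 h after the high-fat meal and at 1 h and 4 h after the low-fat meal, with 1 of 28 genes called in these comparisons together, bhlha15 (1.29 at 1 h after the low-fat meal in the authors' deposited table). Islet and enteroendocrine hormones (26 genes) had 1 call, penkb with 1.4 at 1 h after the low-fat meal in the authors' deposited table, and mitochondrial respiratory chain genes (83 genes), cytosolic ribosomal proteins (73 genes) and goblet cell genes (6 genes) had 0 calls against unfed larvae. As lists, exocrine pancreas at 4 h after the low-fat meal, liver at 4 h after both meals, and ribosomal proteins and goblet cells at 4 h after the high-fat meal passed at a preset correlation of 0.01 and not at 0.05. Liver markers had 1 call at 1 h after the high-fat meal, tdo2b (-1.24), and 1 at 1 h after the low-fat meal, cyp2ad2 (1.58), in the authors' deposited table.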
